A study of Homo sapiens with 6 samples.

How the data were processed

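Poly(A)-selected RNA from 2 human ovarian tumour cell lines, PA-1 (an ovarian teratocarcinoma line) and TOV21G (an ovarian clear cell carcinoma line), was sequenced as 6 stranded libraries. Each line gave 1 library with a scramble short hairpin RNA, called the control, and 1 library with each of 2 lentiviral hairpins against MEX3A, called hairpin 1 and hairpin 2. Per the file headers, the authors deposited for each library an RSEM gene table with the expected count (RSEM's estimated number of reads or read pairs per gene), TPM (transcript abundance scaled to a fixed total), FPKM (fragments scaled by length and total) and the transcript lengths of 39282 genes. Per the labels, reads were trimmed with cutadapt 1.12, aligned to hg38 with STAR 2.5.3a and summarised with RSEM 1.2.31 on RefSeq transcripts. The labels also name edgeR 3.26.8 without saying what it was used for, and they do not state the strand setting of the counting. Genes that share reads with paralogs, pseudogenes or antisense transcripts are therefore less certain than others. The expected counts summed to between 14654628 and 19495162 per library, and 3 counts, the level that a count of 0 allows, corresponded to 0.153 to 0.202 CPM (counts scaled by the TMM-adjusted total of the library, in the unit of edgeR). Counting intervals and floors cover counting error only, since reads carried no molecular identifiers.

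The deposited expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, and filterByExpr on the 4 groups (cell line by hairpin target) kept 16855 genes. The quasi-likelihood F test was fitted with 1 mean per group, which left 2 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The spread came from the 2 hairpins of each line, and each line's single control library was assumed to vary as they did. Nothing in the labels states that the libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries. Hairpins 1 and 2 are different reagents, and their spread includes any difference between reagents. The biological coefficient of variation was 0.295 over both lines, 0.164 in PA-1 fitted alone and 0.387 in TOV21G fitted alone, and the shared value entered every test. The contrasts were knockdown against control in PA-1, the same in TOV21G, the mean of both effects, and the TOV21G effect minus the PA-1 effect. Log2 fold changes are followed by an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of its F statistic in this model.

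Each hairpin was also compared with its control as the series' design text describes it, without a test, as a difference in log2 CPM with a prior count of 2. Genes that differed at least 2-fold in the same direction with both hairpins were counted. Since both differences of a line use the same control, the counts were set beside 100 simulated draws in which no gene differed. All libraries of a line, the control included, varied in these draws as its 2 hairpins did. Relabelling which library of each line was the control gave 9 labelings, and an exact permutation p from them cannot go below 0.111.

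Of 34 gene lists fixed in advance, 32 had at least 3 measured genes and were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, again with an estimated correlation, and with fry. With an estimated correlation the test rested on the 2 residual degrees of freedom, where a call after adjustment is hardly possible. A list that did not pass there is therefore not shown to have moved through correlated genes. Members were counted as passing over all genes and adjusted over the list alone. For each hairpin, list medians were ranked among 10000 random lists matched on expression in 20 bins. The mitochondrial genome list could not be tested because 0 of its 13 symbols were in the files, and the blood cell marker list because 2 of its 16 genes passed the filter. The lists covered p53 targets and regulators, ferroptosis suppressors and drivers, stress responses, the cell cycle, lipid and iron metabolism, inflammation, cell identity, translation and respiration. Several lists share members.

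The named genes followed a rule. They were MEX3A and, per line and direction, the 10 genes with the largest smaller-of-2-hairpins difference among genes with an adjusted p under 0.05, the same sign with both hairpins and a mean of at least 5 CPM in the line. Where fewer than 10 passed, the list was filled to 10 by the same ranking, and those genes are given as not passing. For the mean of both lines, 5 genes per direction were taken by the smallest of the 4 differences. For the difference between lines, only genes past the threshold were to be named, and there were none. Each gene list was described by up to 4 members with the smallest p. CDKN1A, MDM2, SLC7A11, GPX4, TFRC, ACSL4 and FTH1 were always given. Clone-named loci were passed over, and some genes taken by these rules are not reported here.

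The comparisons, tests, lists, naming rule and alternatives were chosen before the data were examined, except where the text says otherwise. The alternatives were the size factors of DESeq2, library size alone, no filter, a stricter filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma with a trend on log2(TPM + 1), unrounded counts, robust shrinkage, each line fitted alone, an additive model, the hairpin number as a block, other prior counts and fold minimums, and leaving out each knockdown library. DESeq2 gave no adjusted p to 1308 genes in PA-1, 4902 in TOV21G, 3595 in the mean and 2288 in the difference. For DESeq2, over all genes therefore means over the genes that had an adjusted p. Leaving out a control ends its line's comparison and gave no value for it. Leaving out a knockdown library leaves 1 hairpin library against 1 control in its line, and the spread then comes from the other line alone. The main test was tested on simulated data in which both lines had the same spread, the one fitted here over both. Of 100 genes changed 4-fold and 100 changed 16-fold, it called 64 and 98 in PA-1, 56 and 97 in TOV21G and 91 and 97 in the mean, with 11, 13 and 12 false calls beside both sets together. The measured spread differed between the lines (0.164 and 0.387 fitted alone). These recoveries therefore need not hold for the real libraries, where 0 calls do not show that large changes were absent. In 5 simulated draws without changed genes, camera called 1 list in all out of 32 per draw. Genes varied independently in these draws, so they do not test the preset correlation or the error rate of lists whose genes vary together.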

Results

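The data were 6 RNA-seq libraries from 2 ovarian tumour lines in which MEX3A, an RNA-binding protein with a RING domain, was depleted with short hairpin RNAs. PA-1 and TOV21G each had 1 control library, 1 with hairpin 1 and 1 with hairpin 2, so the groups held 1 control and 2 knockdown libraries per line. Total expected counts in PA-1 were 15861565 in the control, 15769163 with hairpin 1 and 19495162 with hairpin 2. In TOV21G they were 15694371, 14654628 and 16012602. The title of the series asks about p53 degradation and ferroptosis, an iron-dependent form of cell death by lipid peroxidation.

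MEX3A was lower with each hairpin in each line. In PA-1 the control had 137 CPM, hairpin 1 had 41.2 CPM and hairpin 2 had 54.9 CPM, which is 30.0% and 40.0% of the control. In TOV21G the control had 78.3 CPM, and hairpins 1 and 2 left 40.1 and 33.1 CPM, or 51.2% and 42.3%. The gene lies on the minus strand of chromosome 1 at 156072013 to 156082465 in hg38, with exons at 156081545 to 156081998 and 156072013 to 156077682. The log2 fold change was -1.51 (SE 0.28) in PA-1, -1.10 (SE 0.29) in TOV21G and -1.30 (SE 0.20) in the mean of both lines, with edgeR adjusted p values of 1, 0.417 and 0.547. DESeq2 gave an adjusted p of 0.0478 in PA-1, 0.164 in TOV21G and 0.00142 for the mean. Without TOV21G hairpin 1, edgeR gave -1.24 and an adjusted p of 0.0483 in TOV21G, and -1.38 and 0.0385 for the mean, but TOV21G then held 1 hairpin library against 1 control and its spread was taken from PA-1 (biological coefficient of variation 0.164, against 0.387 in TOV21G). Without TOV21G hairpin 2 the values were -0.97 (adjusted p = 0.157) in TOV21G and -1.24 (adjusted p = 0.12) for the mean, and without either PA-1 hairpin MEX3A did not pass in any contrast. The real labelling was the lowest of 9, an exact permutation p of 0.111, the smallest these libraries allow. Of the other family members, MEX3B, MEX3C and MEX3D had log2 fold changes of 0.20 (SE 0.24), 0.29 (SE 0.17) and -0.08 (SE 0.46) in the mean.

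**Figure D1:**
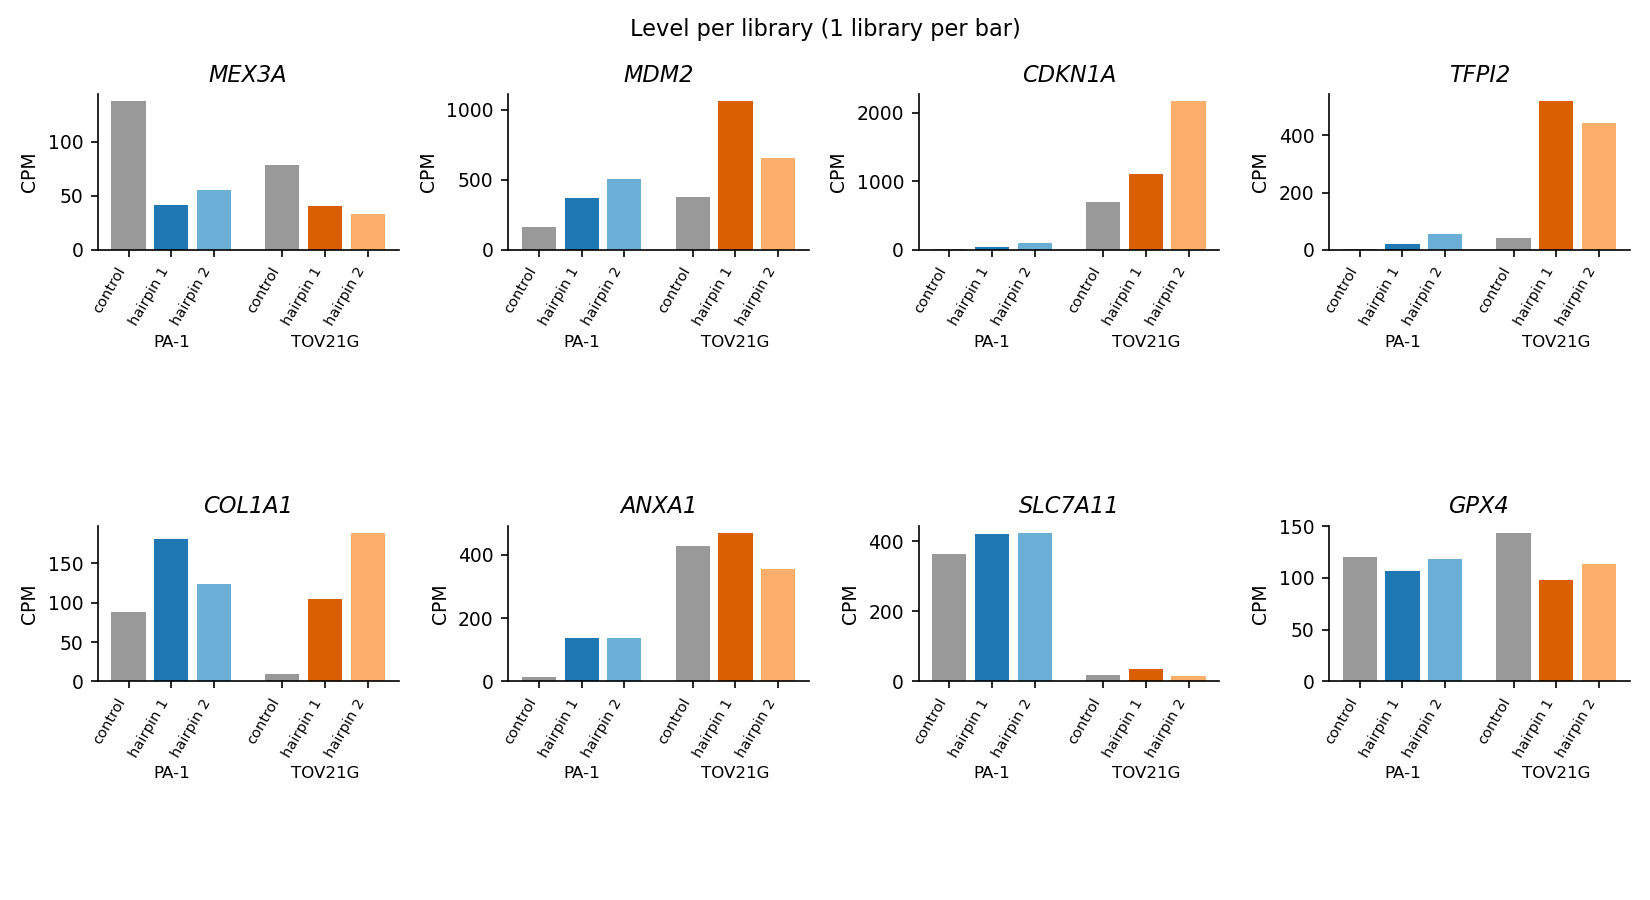
Level of 8 genes in each of the 6 libraries, in CPM (vertical axes starting at 0), grouped by line with the control first and 1 bar per library. MEX3A stood at 137 CPM in the PA-1 control and 41.2 and 54.9 CPM with the hairpins, MDM2 lay above its control level in all 4 hairpin libraries, and COL1A1 in TOV21G stood at 9.03 CPM in the control and 104 and 189 CPM with the hairpins.

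The first comparison asked what MEX3A depletion did in PA-1. Targets of p53 were higher with both hairpins, including MDM2, the ubiquitin ligase that p53 induces, at 367 and 502 CPM against 164 CPM in the control. CDKN1A, the p21 cell cycle inhibitor, stood at 35.4 and 105 CPM against 18.9 CPM. In the same libraries the nuclear RNA NEAT1 was at 270 and 273 CPM against 119 CPM, and ribosomal protein genes took 4.67% and 4.90% of the counts against 5.41%. Genes of DNA replication, mitosis, cholesterol and fatty acid synthesis and ribosomal proteins were lower by small amounts, and inflammatory, interferon, matrix and epithelial genes were higher. These are calls of camera at its preset correlation, which called 9 lists higher and 7 lower of 32. With an estimated correlation camera called 0, and fry called 0, with 1 list at an unadjusted p under 0.05.

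The p53 target list rose in PA-1, with a median log2 fold change of 0.48 over 74 measured genes, 59 of them higher and 3 lower with both hairpins (camera adjusted p = 1.02e-15). The list had an adjusted p = 0.585 with an estimated correlation. At least 2-fold with both hairpins were 6 members, none passed edgeR over all genes or adjusted over the list alone, 10 had an unadjusted p under 0.05, and DESeq2 called 1 over all genes, BTG2. Members with small p values were BTG2, an antiproliferative gene (1.90, SE 0.34), and the kinase PLK2 (1.82, SE 0.52). CDKN1A had 1.89 (SE 0.80) and MDM2 1.41 (SE 0.41). The list of p53 and its regulators had a median of -0.04 and a mean of 0.06 over 13 genes and did not pass (adjusted p = 0.907).

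Replication and division genes fell together in PA-1. Of 48 G1/S and replication genes 37 were lower with both hairpins, with a median of -0.22 (camera adjusted p = 1.16e-05, and adjusted p = 0.672 with an estimated correlation). Examples were the licensing factor CDT1 (-0.84, SE 0.36), UHRF1 (-0.47, SE 0.23) and E2F1 (-0.53, SE 0.27). Of 49 G2/M genes 40 were lower, also with a median of -0.22 (camera adjusted p = 5.05e-06), among them the mitotic kinesin KIF20A (-0.56, SE 0.23) and ASPM (-0.43, SE 0.24). Cholesterol synthesis and uptake fell with a median of -0.26 and 22 of 25 genes lower with both hairpins (camera adjusted p = 0.00018), led by INSIG1 (-0.73, SE 0.37) and CYP51A1 (-0.51, SE 0.27). Fatty acid synthesis fell with a median of -0.28 and 14 of 17 genes lower (camera adjusted p = 0.000545), led by the desaturase SCD (-0.93, SE 0.40) and FASN (-0.58, SE 0.25). Cytosolic ribosomal proteins fell with a median of -0.17 and 63 of 74 genes lower (camera adjusted p = 1.16e-05). The G2/M, cholesterol, fatty acid and ribosomal protein lists each had an adjusted p = 0.585 with an estimated correlation, and in none of the 5 lists did a gene pass edgeR adjusted over the list alone or DESeq2 over all genes.

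Inflammatory, interferon, matrix and epithelial lists rose in PA-1. NF-kB and inflammatory cytokines had a median of 0.74 over 22 genes, 14 of them higher with both hairpins (camera adjusted p = 8.14e-06), with the cytokines IL1A (4.16, SE 0.98) and LIF (1.45, SE 0.38). The interferon list had a median of 0.47 over 37 genes, 20 of them higher with both (camera adjusted p = 8.14e-06), with HERC6 (2.11, SE 0.44) and OAS3 (1.53, SE 0.33). Mesenchymal and matrix genes had a median of 0.35 over 32 genes, 19 of them higher with both (camera adjusted p = 2.87e-05), with the collagens COL5A2 (2.55, SE 0.42) and COL1A2 (1.85, SE 0.45), fibronectin FN1 (1.79, SE 0.46) and the collagen cross-linker LOX (5.20, SE 1.04). Epithelial genes had a median of 0.37 over 22 genes, 11 of them higher with both (camera adjusted p = 0.00455), with the splicing factor ESRP2 (2.70, SE 0.55) and the protease inhibitor SPINT1 (2.26, SE 0.49). These 4 lists each had an adjusted p = 0.585 with an estimated correlation. By edgeR no member passed adjusted over the list alone, while over all genes DESeq2 called 4 matrix genes, COL5A2, FN1 and LOX among them, and 1 of the NF-kB list, IL1A.

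A further 6 lists passed camera in PA-1 but lost the call when 1 library was left out. Without a PA-1 hairpin the spread came from TOV21G alone, so a lost call does not show that 1 library carried the effect. Medians with PA-1 hairpins 1 and 2 were 0.49 and 0.63 for immediate early genes and 0.33 and 0.97 for YAP and TEAD targets. They were 0.19 and 0.33 for hypoxia and glycolysis and 0 and 0.49 for clear cell markers. Immediate early genes (median 0.59, camera adjusted p = 0.000598, FOSL1 1.30 with SE 0.34), YAP and TEAD targets (0.75, camera adjusted p = 0.00101, CCN2 2.04 with SE 0.75) and clear cell carcinoma markers (0.37, camera adjusted p = 0.00884) rose, and each had an adjusted p = 0.585 with an estimated correlation. Hypoxia and glycolysis genes rose too (0.28, camera adjusted p = 0.0275), with an adjusted p = 0.672 with an estimated correlation. Without PA-1 hairpin 2 the adjusted p was 0.116 for the immediate early genes, 0.259 for the YAP and TEAD targets, 0.116 for the clear cell markers and 0.309 for hypoxia and glycolysis. The clear cell markers were also lost without TOV21G hairpin 1 (0.0907), and 2 of their 12 genes passed adjusted over the list alone, TFPI2 (3.50, SE 0.74) and SPP1 (2.39, SE 0.57). Camera ranked the MEX3 family downward (median -0.06 over 4 genes, camera adjusted p = 0.0364), with MEX3A the 1 gene passing adjusted over the list alone. MEX3A is the target of the hairpins, so this call is no result about the rest of the family. The family medians with PA-1 hairpins 1 and 2 were 0.10 and -0.31. The 6 measured replication-dependent histone genes fell (median -0.55, camera adjusted p = 0.0489). Both lists had an adjusted p = 0.585 with an estimated correlation. The family call was lost without any 1 of the 4 knockdown libraries (adjusted p = 0.0559 without PA-1 hairpin 1 and 0.335 without PA-1 hairpin 2, 0.291 and 0.271 without TOV21G hairpins 1 and 2), and the histone call without PA-1 hairpin 1 (0.698), TOV21G hairpin 1 (0.0792) or TOV21G hairpin 2 (0.0734).

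The ferroptosis lists did not pass in PA-1. Ferroptosis suppressors had a median of 0.05 and a mean of 0.11 over 34 genes although camera ranked them downward (adjusted p = 0.907), and drivers a median of -0.03 and a mean of 0.08 over 36 genes (adjusted p = 0.852). SLC7A11, the cystine transporter, stood at 419 and 423 CPM with the hairpins against 364 CPM (0.21, SE 0.52), and GPX4, the lipid peroxide reductase, at 107 and 118 CPM against 121 CPM (-0.10, SE 0.24). The transferrin receptor TFRC had 0.48 (SE 0.35), the lipid ligase ACSL4 -0.13 (SE 0.49) and the ferritin heavy chain FTH1 -0.04 (SE 0.63).

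Among single genes in PA-1, the ranking put LOX, the collagen COL8A1, NAV3, the phospholipid-binding ANXA1, CSMD3, the caveolin CAV2, IL1A, ST8SIA4, IGFBP7 and the neuropeptide galanin (GAL) highest. ANXA1 went from 15.4 to 138 CPM with each hairpin (3.17, SE 0.32), and LOX from 1.76 to 30.8 and 99.7 CPM. Among the lowest it put the Wnt antagonist SFRP1, MEX3A, PKNOX2, ADCY9, BOC, FGFBP3, PCDH8, LRRN3 and EFNB1. SFRP1 went from 353 to 114 and 124 CPM (-1.57, SE 0.54). None of these genes passed edgeR, which called 0 genes in PA-1 (13 with the hairpin number as a block), while 434 of 16855 genes had an unadjusted p under 0.05 against 843 by chance. DESeq2 called 34 genes higher and 2 lower, with LOX, COL8A1, ANXA1, CAV2, IL1A, ST8SIA4, IGFBP7, GAL and MEX3A among them. In the comparison without a test, 566 genes were at least 2-fold higher and 115 lower with both hairpins, against 186 and 130 on average in simulated libraries that share an unchanged control (at most 218 and 151). Part of the excess of higher genes can come from the single control, which cannot be split.

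The second comparison asked the same in TOV21G. Genes of the cell cycle were far lower with both hairpins: all 49 G2/M genes and 47 of 48 G1/S genes lay below the control. The same cells had more mRNA of p53 targets, with MDM2 at 1058 and 654 CPM against 377 CPM and CDKN1A at 1103 and 2168 CPM against 692 CPM. In the same libraries the nuclear RNA MALAT1 was at 9429 and 18455 CPM against 4315 CPM, NEAT1 at 1133 and 1068 CPM against 361 CPM, and ribosomal protein genes took 4.41% and 4.10% of the counts against 4.85%. By camera at its preset correlation 7 lists were higher and 7 lower, among them matrix genes higher and ferroptosis suppressors lower. With an estimated correlation camera called 0 lists, and fry called 0, with 4 at an unadjusted p under 0.05.

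The G2/M list fell in TOV21G with a median log2 fold change of -1.21, 32 of 49 genes at least 2-fold lower with both hairpins and 47 passing adjusted over the list alone (camera adjusted p = 5.22e-45). Its smallest p values belonged to the kinase PBK (-1.66, SE 0.24), the securin PTTG1 (-1.53, SE 0.23), UBE2C (-1.50, SE 0.23) and KIF20A (-1.40, SE 0.23). The G1/S list fell with a median of -1.10, 19 of 48 genes at least 2-fold lower and 26 passing adjusted over the list alone (camera adjusted p = 3.91e-29), with the ribonucleotide reductase subunit RRM2 (-1.64, SE 0.22), the replication factor CDC45 (-1.71, SE 0.28), E2F2 (-2.21, SE 0.37) and the thymidine kinase TK1 (-1.46, SE 0.25). Both lists had an adjusted p = 0.58 with an estimated correlation. Over all genes, none of their members passed edgeR, while DESeq2 called 28 of the G2/M list and 11 of the G1/S list lower, PTTG1, PBK, KIF20A, RRM2 and CDC45 among them. The 6 measured replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, rose with a median of 1.13 (camera adjusted p = 0.017), led by H1-2 at 52.9 and 57.2 CPM against 24.6 CPM. That list had an adjusted p = 0.614 with an estimated correlation and 0.275 at the preset one without TOV21G hairpin 2.

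The p53 target list rose with a median of 0.67, 58 of 74 genes higher and 2 lower with both hairpins and 11 at least 2-fold higher (camera adjusted p = 3e-13). It had an adjusted p = 0.58 with an estimated correlation, and by edgeR 28 members had an unadjusted p under 0.05 while 0 passed adjusted over the list alone. DESeq2 called 5 members higher over all genes, among them CD82 and ACER2. CD82, a tetraspanin (2.09, SE 0.33), the ceramidase ACER2 (1.72, SE 0.36) and TP53INP1 (1.25, SE 0.26) had the smallest p. The fold changes were 1.24 (SE 0.77) for CDKN1A and 1.18 (SE 0.41) for MDM2. The list of p53 and its regulators did not pass (median 0.15, adjusted p = 0.663).

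Ferroptosis suppressors fell with a median of -0.35, 20 of 34 genes lower and 1 higher with both hairpins (camera adjusted p = 0.00782), with an adjusted p = 0.58 with an estimated correlation. The member with the smallest p was FANCD2, a DNA crosslink repair gene (-1.13, SE 0.25), followed by the iron-sulfur protein CISD2 (-0.90, SE 0.28), the ketosteroid reductase AKR1C2 (-1.76, SE 0.65) and SCD (-0.90, SE 0.40), and 0 passed edgeR adjusted over the list alone or DESeq2 over all genes. SLC7A11 was at 34.9 and 14.4 CPM against 17.8 CPM, so its hairpins lay on either side of the control, and GPX4 was at 98.3 and 113 CPM against 143 CPM (-0.44, SE 0.24). Ferroptosis drivers did not pass (median 0.08, adjusted p = 0.565), and TFRC (-0.37, SE 0.34), ACSL4 (0.56, SE 0.51) and FTH1 (0.10, SE 0.63) had errors close to their size or above it. NRF2 targets had a median of -0.11 and did not pass (adjusted p = 0.0525), with the quinone reductase NQO1 at -1.57 (SE 0.31). ATF4 targets did not pass either (-0.14, adjusted p = 0.0925).

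Of the metabolic lists in TOV21G, cholesterol synthesis and uptake fell (median -0.28, 12 of 25 lower with both hairpins, camera adjusted p = 0.0128), with the sterol isomerase EBP (-0.99, SE 0.27) and the thiolase ACAT2 (-0.86, SE 0.28). Ribosome biogenesis and MYC targets fell (median -0.26, 17 of 26 lower, camera adjusted p = 0.0111), with fibrillarin FBL (-1.42, SE 0.38). Both had an adjusted p = 0.58 with an estimated correlation, and 0 genes passed edgeR adjusted over either list alone or DESeq2 over all genes. Nuclear oxidative phosphorylation genes fell (median -0.29, 26 of 37 lower, camera adjusted p = 0.00137), and ATP5F1C, an ATP synthase subunit, passed adjusted over the list alone (-1.54, SE 0.24). Hypoxia and glycolysis genes fell (median -0.39, 15 of 28 lower, camera adjusted p = 0.00782), although the median was -0.02 with hairpin 1 and -0.86 with hairpin 2, with EGLN3 (-2.11, SE 0.35) and the hexokinase HK2 (-1.20, SE 0.22) passing adjusted over the list alone. These last 2 lists had an adjusted p = 0.646 with an estimated correlation, and without TOV21G hairpin 2 the adjusted p was 0.0734 for oxidative phosphorylation and 0.769 for hypoxia and glycolysis.

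Matrix genes rose in TOV21G with a median of 0.93 over 32 genes, 18 of them higher with both hairpins (camera adjusted p = 0.000208), and 3 genes passed adjusted over the list alone, among them COL1A1 (4.02, SE 0.56) and COL5A1 (2.37, SE 0.48). The matrix medians per hairpin were lower, at 0.44 and 0.73 with hairpins 1 and 2. YAP and TEAD targets rose with a median of 0.86, 14 of 22 higher with both (camera adjusted p = 0.00233), with NUAK2 (1.29, SE 0.25) and ANKRD1 (5.97, SE 2.05). Epithelial genes rose with a median of 0.69, 12 of 22 higher with both (camera adjusted p = 0.0219), with SPINT1 (1.67, SE 0.46). These 3 lists had an adjusted p = 0.58 with an estimated correlation, and without TOV21G hairpin 2 the adjusted p was 0.0747 for the matrix genes and 0.25 for the epithelial genes. The interferon list (median 0.38, camera adjusted p = 0.0294) and the NF-kB list (median 0.36, camera adjusted p = 0.0399) rose as well, with an adjusted p = 0.646 and an adjusted p = 0.661 with an estimated correlation. The interferon list lost the call without TOV21G hairpin 1, and the NF-kB list without TOV21G hairpin 2, with the spread then taken from PA-1 alone. Medians with TOV21G hairpins 1 and 2 were 0.45 and 0.26 for the interferon list and 0.12 and 0.62 for the NF-kB list. Immediate early genes did not pass (median 0.72, adjusted p = 0.052). Clear cell carcinoma markers did not pass (median -0.12, mean 0.37, camera downward, adjusted p = 0.0962), with ANXA4 (-1.71, SE 0.22), the glypican GPC3 (-2.26, SE 0.31) and FXYD2 (-1.99, SE 0.35) lower and TFPI2 (3.55, SE 0.72) higher adjusted over the list alone. Their medians per hairpin were lower, at -0.68 and -0.51 with TOV21G hairpins 1 and 2. Wnt targets did not pass (median -0.03, adjusted p = 0.105), with the Wnt antagonist DKK1 (-1.99, SE 0.38) passing adjusted over the list alone.

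Among single genes in TOV21G, the ranking put the chaperone HSPB8, SMOC1, the cytokine IL11, COL1A1, TFPI2, TXNIP, IGDCC4, TLR6 and FLRT2 among the highest. The control held only 3 counts of HSPB8, 5 of SMOC1, 4 of IL11 and 8 of TLR6, so the sizes of their rises are uncertain. COL1A1 went from 9.03 to 104 and 189 CPM, TFPI2 from 41.2 to 519 and 443 CPM and TXNIP, a thioredoxin inhibitor, from 8.96 to 113 and 94.4 CPM (3.53, SE 0.43). Among the lowest were the chemokine CXCL12, the protease HTRA1, CCN3, FAM149A, RASSF6, PRODH, CYS1, TFCP2L1 and CHDH. CXCL12 went from 24.2 to 0.527 and 0.672 CPM (-5.32, SE 0.48) and HTRA1 from 232 to 24.3 and 22.5 CPM (-3.31, SE 0.40). None of these genes passed edgeR, which called 0 genes in TOV21G (36 with the hairpin number as a block), with a smallest adjusted p of 0.382, while 1612 genes had an unadjusted p under 0.05 against 843 by chance. DESeq2 called 94 genes higher and 132 lower, with all of these genes but HSPB8 among them. Without TOV21G hairpin 1, edgeR called 1489 genes, 687 higher and 802 lower, on 1 residual degree of freedom. In the comparison without a test, 718 genes were at least 2-fold higher and 567 lower with both hairpins. Simulated libraries with a shared unchanged control gave 756 and 541 on average, and at most 813 and 586. The simulated control was given the spread between the 2 hairpins, which includes any difference between reagents. Counts within the simulated range therefore do not show that no genes changed with both hairpins.

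The third comparison asked what both lines had in common. By camera at its preset correlation, targets of p53 were higher (46 of 74 with all 4 hairpins), G2/M and G1/S genes lower (40 of 49 and 36 of 48) and matrix genes higher (12 of 32), among 8 lists higher and 8 lower. With an estimated correlation camera called 0 lists, and fry called 0, with 4 at an unadjusted p under 0.05. TFPI2, a Kunitz-type protease inhibitor, went from 3.34 to 20.2 and 55.3 CPM in PA-1 and from 41.2 to 519 and 443 CPM in TOV21G, a mean log2 fold change of 3.52 (SE 0.51). COL1A1 had a mean of 2.40 (SE 0.36), and MDM2 1.30 (SE 0.29).

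**Figure D2:**
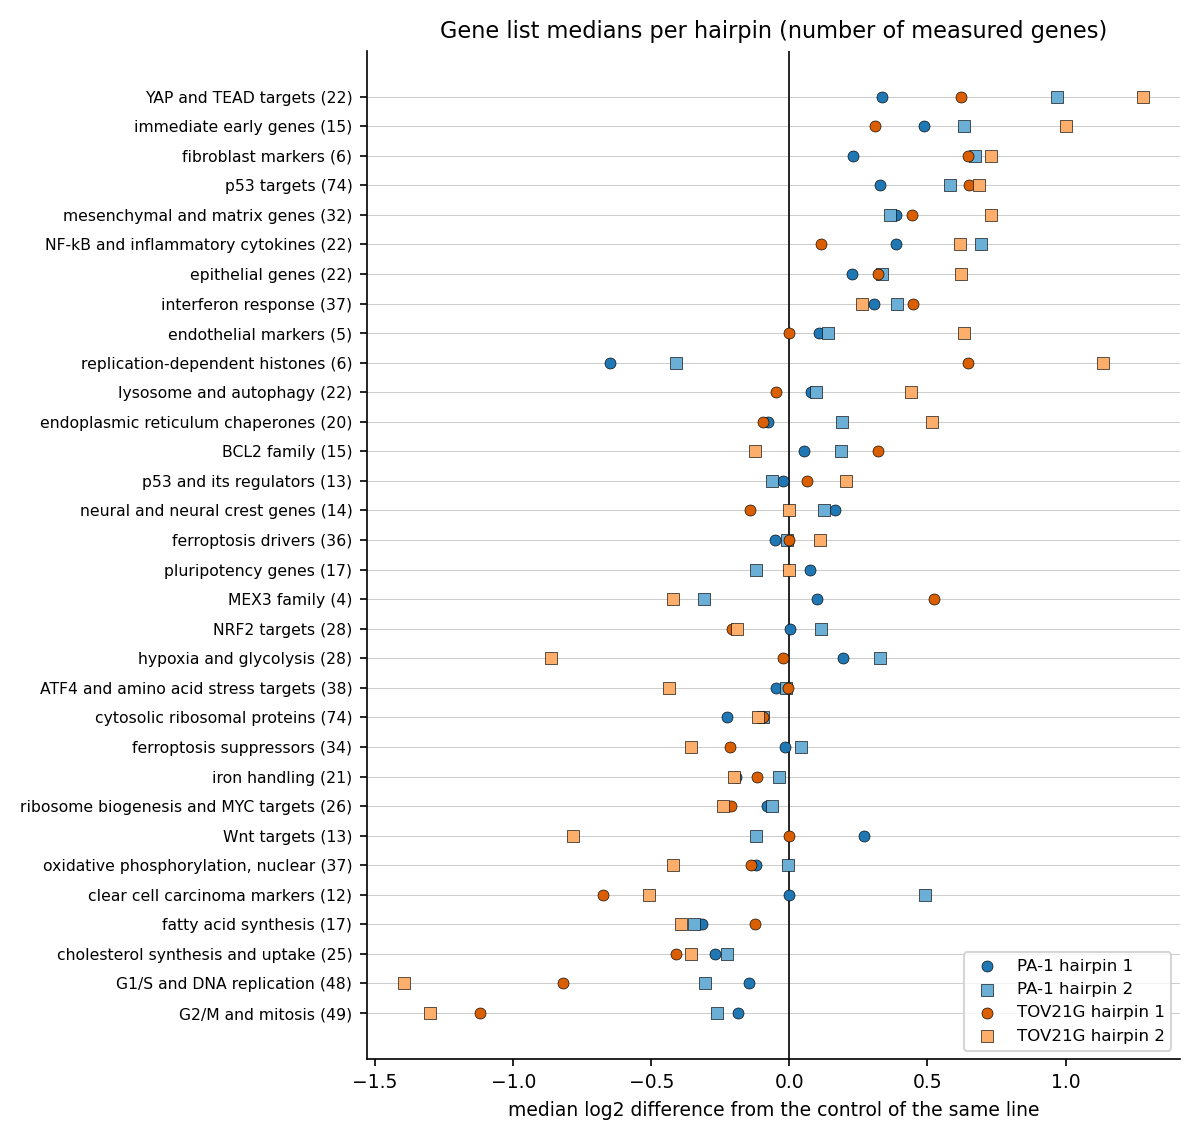
Median log2 difference from control of gene lists fixed in advance, with 1 row per list (its number of measured genes in brackets), 1 point per hairpin and line and 0 marking the control level. The p53 targets lay above 0 with all 4 hairpins, and the G2/M and G1/S lists lay below 0 with all 4 and farther below in TOV21G.

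In the mean of both lines, the p53 target list rose with a median of 0.58, 73 of 74 genes positive and 46 higher with all 4 hairpins (camera adjusted p = 4.68e-21). Passing adjusted over the list alone were 4 genes, among them BTG2 (1.42, SE 0.23), ACER2 (1.47, SE 0.25) and TP53INP1 (1.06, SE 0.18), while CDKN1A had 1.57 (SE 0.55). The G2/M list fell with a median of -0.70, 40 of 49 genes lower with all 4 hairpins and 43 passing adjusted over the list alone (camera adjusted p = 4.81e-42). The G1/S list fell with a median of -0.65, 36 of 48 genes lower with all 4 and 16 passing adjusted over the list alone (camera adjusted p = 2.91e-28), with E2F1 (-1.06, SE 0.19) and CDT1 (-1.32, SE 0.25). Mesenchymal and matrix genes rose with a median of 1.06, 12 of 32 higher with all 4 and 9 passing adjusted over the list alone (camera adjusted p = 1.31e-07), with COL1A1 (2.40, SE 0.36), COL5A2 (1.74, SE 0.30) and FN1 (2.04, SE 0.35). The matrix medians per hairpin, which use a larger prior count, were lower, at 0.39 and 0.37 in PA-1 and 0.44 and 0.73 in TOV21G. YAP and TEAD targets rose with a median of 0.80 (camera adjusted p = 6.73e-05), with NUAK2 (0.74, SE 0.17) and CCN2 (2.02, SE 0.53). All 5 lists had an adjusted p = 0.463 with an estimated correlation. In the exact permutation of the control within each line, the real labelling was the most extreme of 9 (p = 0.111, the smallest possible) for the p53 (0.54, highest other 0.41), G1/S (-0.67, highest other 0.57), G2/M (-0.72, highest other 0.58) and matrix lists (0.47, highest other 0.34), and for YAP and TEAD targets it was second (0.71, highest other 0.81).

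Ferroptosis suppressors fell slightly in the mean, with a median of -0.16, 7 of 34 genes lower and 0 higher with all 4 hairpins (camera adjusted p = 0.0377, and adjusted p = 0.463 with an estimated correlation). FANCD2 (-0.59, SE 0.18), CISD2 (-0.65, SE 0.20) and SCD (-0.91, SE 0.28) had the smallest p. The call was lost without PA-1 hairpin 1 (median -0.15, adjusted p = 0.0605), without TOV21G hairpin 2 (median -0.12, adjusted p = 0.126) and under the stricter filter (median -0.14, adjusted p = 0.114). In the exact permutation 3 of 9 labelings were as extreme as the real one (p = 0.333). Drivers did not pass (median 0.03, adjusted p = 0.797), with SAT1, a polyamine acetyltransferase, at 1.03 (SE 0.27). SLC7A11 had 0.34 (SE 0.38), GPX4 -0.27 (SE 0.17), TFRC 0.06 (SE 0.24), ACSL4 0.21 (SE 0.35) and FTH1 0.03 (SE 0.45).

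**Figure D3:**
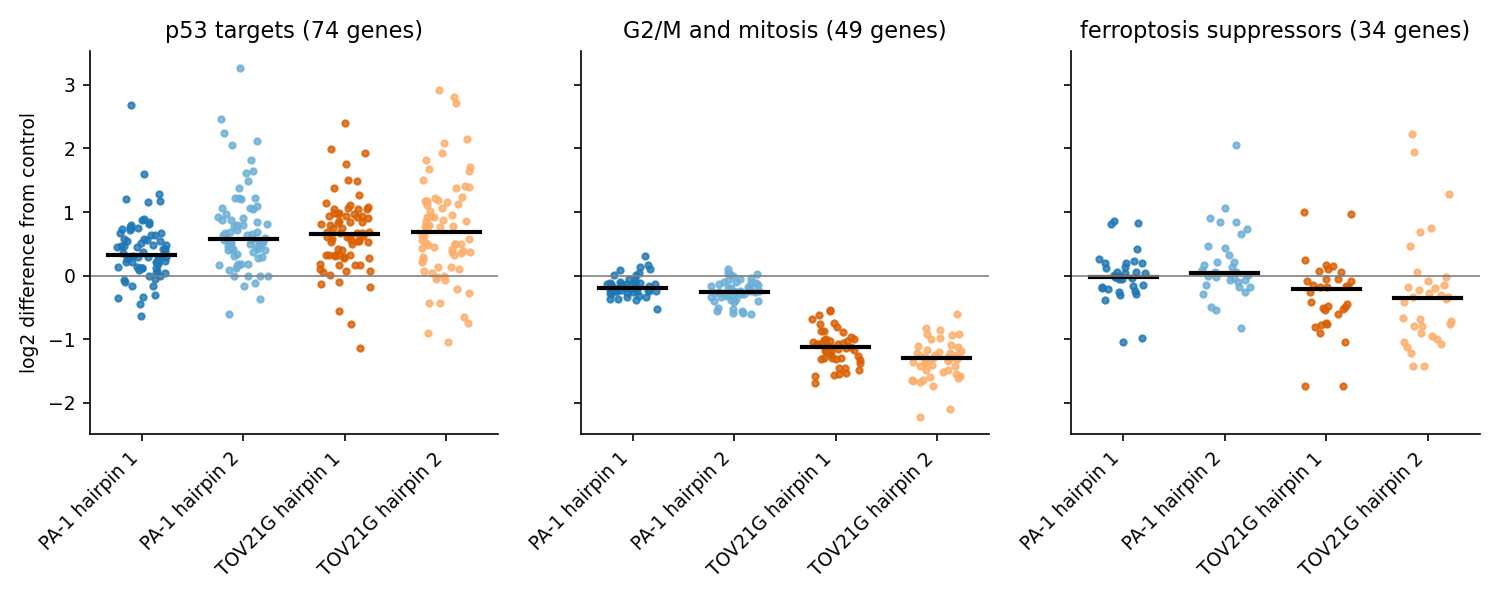
Log2 difference from the control of the same line for each member of the p53 target, G2/M and ferroptosis suppressor lists, with 1 point per gene, 1 column per hairpin and line, a black bar at the list median and a grey line at 0. Of the 74 p53 targets 46 lay above 0 with all 4 hairpins, of the 49 G2/M genes 40 lay below 0 with all 4, and of the 34 ferroptosis suppressors 7 lay below 0 with all 4.

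Other lists passed camera in the mean as well. Cholesterol synthesis and uptake fell (median -0.33, 12 of 25 lower with all 4 hairpins, camera adjusted p = 0.000127), as did ribosome biogenesis (-0.15, camera adjusted p = 0.00577), and epithelial genes rose (0.60, camera adjusted p = 0.000931), with SPINT1 passing adjusted over the list alone (1.97, SE 0.34). These 3 had an adjusted p = 0.463 with an estimated correlation. The interferon list rose (0.61, camera adjusted p = 0.000158) and fatty acid synthesis fell (-0.18, camera adjusted p = 0.00238), both with an adjusted p = 0.54 with an estimated correlation. Per hairpin the interferon medians were lower, at 0.31 and 0.39 in PA-1 and 0.45 and 0.26 in TOV21G. The NF-kB list rose (0.65, camera adjusted p = 0.000377), with an adjusted p = 0.607 with an estimated correlation. Ribosomal proteins fell (-0.14, camera adjusted p = 0.000281), oxidative phosphorylation genes fell (-0.17, camera adjusted p = 0.00102) with ATP5F1C passing adjusted over the list alone (-1.09, SE 0.17), and immediate early genes rose (0.65, camera adjusted p = 0.00131). These 3 had an adjusted p = 0.631 with an estimated correlation. Fibroblast markers rose (1.41 over 6 genes, camera adjusted p = 0.0406), with an adjusted p = 0.463 with an estimated correlation and with COL1A1 and COL1A2 (1.39, SE 0.28) passing adjusted over the list alone. Per hairpin the fibroblast medians were lower, at 0.23 and 0.67 in PA-1 and 0.65 and 0.73 in TOV21G. The interferon call was lost without TOV21G hairpin 1 (adjusted p = 0.062), the immediate early call without PA-1 hairpin 2 (0.0511) or TOV21G hairpin 2 (0.0706), and the fibroblast call without PA-1 hairpin 2 (0.2), TOV21G hairpin 1 (0.166) or TOV21G hairpin 2 (0.538). In the exact permutation 4 of 9 labelings were as extreme as the real one for fatty acid synthesis (p = 0.444), 3 for oxidative phosphorylation (p = 0.333) and 2 each for the interferon, NF-kB and immediate early lists (p = 0.222), and for the other 5 lists of this paragraph the real one was the most extreme (p = 0.111).

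The remaining lists did not pass in the mean. Their median log2 fold changes and camera adjusted p values were 0.04 and 0.797 for p53 and its regulators, -0.01 and 0.267 for NRF2 targets, -0.08 and 0.17 for ATF4 targets, 0.13 and 0.17 for endoplasmic reticulum chaperones, and -0.06 and 0.179 for iron handling. They were -0.11 and 0.241 for hypoxia and glycolysis (mean 0.06), 0.41 and 0.656 for pluripotency genes, 0.17 and 0.908 for neural genes (camera downward), 0.40 and 0.656 for clear cell markers, and -0.02 and 0.414 for Wnt targets (mean 0.07). Per hairpin the pluripotency medians were 0.08 and -0.12 in PA-1 and 0 and 0 in TOV21G. The clear cell medians were 0 and 0.49 in PA-1 and -0.68 and -0.51 in TOV21G. Median log2 fold changes and camera adjusted p values of the other lists follow. They were 0.11 and 0.611 for the BCL2 family, 0.06 and 0.426 for the MEX3 family (mean -0.22, camera downward), 0.16 and 0.207 for lysosome and autophagy genes, 0.24 and 0.301 for histones and 0.48 and 0.656 for endothelial markers.

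Among single genes, TFPI2, ANKRD1, CPA4 and MARCHF4 were among the 5 highest by the ranking, and the kinase PRKCB, PKNOX2, MEX3A and the transcription factor TEF among the 5 lowest. ANKRD1 had 4.29 (SE 1.28), PRKCB -1.49 (SE 0.35) and TEF -1.05 (SE 0.21). In TOV21G, PKNOX2 had 2 counts in the control and 0 with both hairpins, so only its PA-1 values can be read as a difference. The TOV21G control also held only 5 counts of ANKRD1, 6 of CPA4 and 3 of MARCHF4. The PA-1 control held 1 count of CPA4. The sizes of these rises are therefore uncertain. None of these genes passed edgeR, which called 0 genes in the mean (22 with the hairpin number as a block), with a smallest adjusted p of 0.547, while 1383 genes had an unadjusted p under 0.05. DESeq2 called 96 genes higher and 37 lower, among them TFPI2, ANKRD1, COL1A1, MDM2 and MEX3A. Without TOV21G hairpin 1, edgeR called 526 genes, 274 higher and 252 lower. At least 2-fold with all 4 hairpins were 76 genes higher and 10 lower, against 24.1 and 3.87 if the lines were independent. Across 16855 genes, which are not independent replicates, the differences of the same hairpin in the 2 lines had a Pearson correlation of 0.17 for hairpin 1 and 0.26 for hairpin 2, and those of different hairpins 0.14 and 0.10, while within a line the 2 hairpins, which share a control, had 0.64 in PA-1 and 0.45 in TOV21G.

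The fourth comparison tested the TOV21G effect minus the PA-1 effect. Replication and mitosis genes were lower by more in TOV21G, with PTTG1 at -1.58 (SE 0.33), PBK at -1.50 (SE 0.36) and RRM2 at -1.76 (SE 0.33) for the difference. The G2/M list had a median difference of -0.96 (camera adjusted p = 1.85e-32) and the G1/S list -0.86 (camera adjusted p = 5.63e-18), each with an adjusted p = 0.894 with an estimated correlation. Of the 32 lists fry called 0 for the difference, with 2 at an unadjusted p under 0.05. The hypoxia and glycolysis list differed by -0.62 (camera adjusted p = 0.000284), with EGLN3 at -2.63 (SE 0.49), ferroptosis suppressors by -0.26 (camera adjusted p = 0.0247), with FANCD2 at -1.08 (SE 0.36), clear cell markers by -1.09 (camera adjusted p = 0.0247) and the 6 histone genes by 1.82 (camera adjusted p = 0.000345). These 4 lists also had an adjusted p = 0.894 with an estimated correlation. Oxidative phosphorylation genes differed by -0.23 (camera adjusted p = 0.044, and adjusted p = 0.899 with an estimated correlation). In the clear cell list ANXA4 (-2.46, SE 0.33), the osteopontin gene SPP1 (-3.55, SE 0.74) and GPC3 (-1.99, SE 0.45) passed adjusted over the list alone.

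The p53 targets did not pass for the difference (median 0.17, adjusted p = 0.0849), but without PA-1 hairpin 2 the median was 0.33 and the adjusted p 0.00212, and with the hairpin number as a block they were 0.14 and 0.0442. Without PA-1 hairpin 2 the adjusted p was 0.103 for ferroptosis suppressors, 0.426 for clear cell markers and 0.112 for oxidative phosphorylation, and without TOV21G hairpin 1 it was 0.679 for clear cell markers. Without TOV21G hairpin 2 it was 0.162 for ferroptosis suppressors, 0.162 for hypoxia and glycolysis, 0.073 for clear cell markers and 0.354 for oxidative phosphorylation, and 4 lists passed in all. Under the stricter filter ferroptosis suppressors had an adjusted p of 0.0598. For single genes edgeR called 0 for the difference, with 642 at an unadjusted p under 0.05, and DESeq2 called 6 higher and 13 lower. Among these, LOX (-5.55 by DESeq2) and ANXA1 (-3.19) differed toward PA-1, and COL1A1 (3.27) and SMOC1 (5.74) toward TOV21G.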

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

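The tests of library scaling, of a control out of place, of effects shared by targeting hairpins, of a single TOV21G hairpin, of nuclear RNA and of the growth state of the TOV21G control were chosen after the results were seen, and those of GC content and length, depth and mixing were written down before their results were seen. Each result listed first was taken up because the effect in TOV21G and the effect in PA-1 differed. Bootstrap intervals in this section came from 2000 draws over genes and not over libraries. They treat genes as independent and leave out variation between cultures and between controls.

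By the camera test of the difference, 7 lists differed between lines, given as the median TOV21G minus PA-1 log2 fold change. The G2/M list had -0.96, the G1/S list -0.86, hypoxia and glycolysis -0.62, clear cell carcinoma markers -1.09, ferroptosis suppressors -0.26, oxidative phosphorylation -0.23 and the 6 histone genes 1.82, and 0 of them passed with an estimated correlation, with adjusted p values of 0.894 to 0.899. A further 7 named genes had estimates on one side of the control with both hairpins of PA-1 and on the other side with both of TOV21G. Their differences were 1.78 for EFNB1, 5.68 for SMOC1, 5.47 for IGDCC4, -4.67 for HTRA1, -6.96 for RASSF6, -7.50 for TFCP2L1 and -0.85 for TFRC. The opposite directions themselves were not tested. In the test of the difference, edgeR called 0 of these 7, and DESeq2 called SMOC1, IGDCC4 and HTRA1. For 3 of the 7 a move in PA-1 with both hairpins was not established. RASSF6 had 0 counts in the PA-1 control and 1 and 4 with the hairpins, and TFCP2L1 had 0 and then 2 and 9, so their differences between lines depend on the prior count and are not sizes. HTRA1 had 13 counts with PA-1 hairpin 1 against 8, a fold with a counting interval of 0.60 to 4.36, and 35 against 8 with hairpin 2, an interval of 1.61 to 8.82. The TOV21G side of TFRC rested mostly on hairpin 1 (log2 -0.74), since with hairpin 2 it was at 0.955 of the control (log2 -0.07).

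The p53 targets lay above control with all 4 hairpins. The tables argue against library scaling, since a scaling factor moves all genes alike and the list median exceeded the median of the other genes expressed in the line by at least 0.34 (bootstrap interval from 0.29), and against GC content or transcript length, since a fit on both left a median of at least 0.27 (from 0.18). A single control out of place is argued against because the list median was above all random lists in each comparison (lowest percentile 100), and 2 of these use the other line's control, although both controls deviating alike would remain. RNA quality or a larger share of nuclear RNA in the hairpin libraries cannot be told apart from the rest. The median over 8 nuclear RNAs was at least 0.244 above control with each of the 4 hairpins, with a bootstrap interval of -0.48 to 1.13 for TOV21G hairpin 1. PVT1, 1 of the 8, also belongs to the p53 target list (0.65 and 0.49 in PA-1, 0.74 and 0.13 in TOV21G). The 2 sets are therefore not separate, and this median cannot decide between the explanations. Handling or off-target effects shared by targeting hairpins and an effect of MEX3A loss cannot be told apart, since there was no second scramble library and no rescue, and the exact permutation p of 0.111 is the smallest possible.

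Replication and mitosis genes were lower in TOV21G by more than in PA-1. The tables argue against GC content or length, since the median difference over both lists was -0.95 before and -0.85 after the fit (bootstrap interval -0.91 to -0.79), and against a single TOV21G hairpin library as the cause, since the smallest gap between a TOV21G and a PA-1 hairpin was -0.78. RNA quality or a larger share of nuclear RNA in the TOV21G hairpin libraries cannot be told apart from the rest, since MALAT1 was higher by 1.21 and NEAT1 by 0.42 in TOV21G than in PA-1, while the median over 8 nuclear RNAs was 0.067 with a bootstrap interval of -0.13 to 0.84. The growth state of the TOV21G control culture and a difference between the cell lines cannot be told apart, since there was 1 control library per line (exact permutation p of 0.111, the smallest possible). The difference between the lines as such stays untested among the open explanations.

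TOV21G hairpin 2 was farther from its control than hairpin 1, with 3900 against 2794 genes at least 2-fold away, a ratio of 1.40. Thinning to equal depth left a ratio of 1.40, although it moved little because the depths were already close. Over the 15060 genes with a GC value the ratio was 1.47 before the fit on GC content and length and 1.49 after it (bootstrap interval 1.44 to 1.56), which argues against that bias as the whole cause, although the fit explained at most 0.888% of the variance of a comparison. Mixing with PA-1 RNA is argued against because 24 genes abundant in PA-1 reached 0.238% of their PA-1 level in this library, beside 0.0354% with hairpin 1 and 0.0257% in the control. No biological explanation was tested, and a difference between the reagents or cultures stays open.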

How the results depend on the processing

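The minimum of 5 CPM was chosen after the data were seen, and all other alternatives were chosen before. No result was counted as reversed under any alternative run, but a change of sign was counted as the same where neither value passed the threshold. The median of ferroptosis suppressors in PA-1, for example, was 0.05 in the main run and -0.01 without PA-1 hairpin 2, and passed in neither. For named genes, 2805 values were counted as the same, which does not show that each kept its direction, and 143 passed only under an alternative.

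The counts of genes called depended on the test. DESeq2 called 36 genes in PA-1, 226 in TOV21G, 133 in the mean and 19 in the difference, where edgeR called 0, and gave MEX3A -1.53 in PA-1 and -1.31 in the mean, both past the threshold. DESeq2 also adjusted over fewer genes than edgeR, since it gave some genes no adjusted p. The cause of the difference in calls was not tested. Without TOV21G knockdown replicate 1 (hairpin 1), edgeR called 1489 genes in TOV21G and 526 in the mean, and MEX3A passed at -1.24 and -1.38. The spread then came from PA-1 alone by construction, whose coefficient of variation was 0.164 against 0.387 in TOV21G. Leaving out each knockdown library in turn gave 0 to 1489 calls in TOV21G and 0 to 526 in the mean, and MEX3A values of -1.24 to -0.97 in TOV21G and -1.41 to -1.21 in the mean. The other alternatives gave 0 calls in every contrast, apart from the block.

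The hairpin number marks the same reagent in both lines, and the labels do not say whether it also marks a shared culture or day. With the hairpin number as a replicate block, which left 1 residual degree of freedom, edgeR called 13 genes in PA-1, 36 in TOV21G, 22 in the mean and 0 in the difference, and the p53 list passed for the difference with a median of 0.14. The deviations of hairpin 1 from its group mean had a correlation of 0.24 between lines over 16855 genes, with only 2 pairs.

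With an estimated correlation, camera called 0 lists in each contrast. That setting rested on 2 residual degrees of freedom and could hardly call a list. Its 0 calls therefore do not show that correlated genes made the list shifts. The medians, which that setting does not move, were 0.48, 0.67 and 0.58 for p53 targets in PA-1, TOV21G and the mean. For G1/S they were -0.22, -1.10, -0.65 and -0.86 in PA-1, TOV21G, the mean and the difference, and for G2/M -0.22, -1.21, -0.70 and -0.96. For ferroptosis suppressors they were -0.35, -0.16 and -0.26 in TOV21G, the mean and the difference. Under the stricter filter ferroptosis suppressors lost the call in the mean (-0.14) and in the difference (-0.23), and the cause was not tested. Leaving out each knockdown library gave that list medians of -0.18 to -0.12 in the mean and -0.54 to -0.15 in the difference, gave p53 targets 0.12 to 0.33 in the difference, and gave 4 to 10 lists called in the difference.

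The counts of genes at least 2-fold higher and lower with both hairpins moved with the weight given to low counts. In PA-1, the higher count was 363 with a prior count of 5, 326 under the stricter filter, 204 on log2(TPM + 1), 137 at 5 CPM or more and 1230 at a fold minimum of 1.5. The lower count was 61, 50, 22, 13 and 461 in the same order, and 181 with a prior count of 0.5. In TOV21G, the higher count was 462, 427, 270, 197 and 1596, and the lower count was 215 on log2(TPM + 1), 284 at 5 CPM or more and 1421 at 1.5-fold. With 1 hairpin left out, fewer libraries need to agree by construction, and the counts were 942 to 1172 higher and 369 to 418 lower in PA-1 and 1468 to 2093 higher and 1326 to 1807 lower in TOV21G.

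At 14654628 to 19495162 counts per library, genes under 0.153 to 0.202 CPM lay below the floor of 3 counts.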

Other observations

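The test of TGF-beta targets was chosen after the genes at least 2-fold higher with all 4 hairpins had been seen, and its member list and prediction were written before the values of its members were looked up. Among the 76 genes at least 2-fold higher with all 4 hairpins were PMEPA1, IL11, INHBA, CDKN2B, FN1 and ACTA2, genes that TGF-beta is known to induce in many cell types. They were chosen here after their values were seen. The level of IL11, a cytokine of the IL6 family, was 0.260 CPM (4 counts) in the TOV21G control and 4.75 and 63.4 CPM with the hairpins.

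A hypothesis from this is that TGF-beta signalling may be higher after MEX3A depletion. A list of 24 other TGF-beta targets, chosen without the genes at least 2-fold higher with all 4 hairpins, was tested against random lists matched on expression. Its median log2 difference from control was 0.27 and 0.36 with PA-1 hairpins 1 and 2 and 0.26 and 0.85 with TOV21G hairpins 1 and 2, with 18, 14, 16 and 20 of the 24 genes higher. The lowest percentile among random lists was 99.21, so the targets were higher than random genes in each of the 4 comparisons, which is consistent with the hypothesis. The theme was found in the same libraries, 4 of the 24 genes also belong to lists described earlier, and both hairpins of a line share a control. The same values could come from handling, from the virus or from cell density, none of which was tested.

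In PA-1, pluripotency genes did not pass as a list (median -0.04, camera adjusted p = 0.854), with POU5F1 at 1.30 (SE 0.45). Neural and neural crest genes did not pass either (median 0.22, adjusted p = 0.297), with TUBB3 at 1.04 (SE 0.31) and GAP43 at 1.25 (SE 0.35). In TOV21G, the BCL2 family did not pass (median 0.15, adjusted p = 0.637), with the p53 target BBC3 at 1.34 (SE 0.36) and BCL2 at -1.16 (SE 0.32).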
